A study of Mus musculus with 2 samples.

How the data were processed

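MicroRNA sequencing of mouse facial prominence tissue at embryonic day 13.5 was available as 2 libraries, which the labels name biological replicates 1 and 2 of 1 group. The tissue came from embryos of both sexes of the B6NCrl strain, per the labels, and RNA shorter than 30 bases was sequenced. The deposited values were whole-number read counts per annotated miRNA gene, in 3 columns per file, made by the authors on the mm10 build with GENCODE release M4, per the deposited description files. The columns hold counts without regard to strand, counts on the strand of the gene and counts on the opposite strand, and 4 further lines give read classes that belong to no gene. This reading rests on the file layout, because the files have no header. In every gene line the first column equalled the sum of the other 2 exactly (0 exceptions among 1973 genes). The aligner, its settings and the trimming are not given in the sources used here. Reads with more than 1 place in the genome stand in a class of their own, so gene counts hold uniquely placed reads, and mature sequences encoded at several loci are undercounted.

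The same-strand column was used, chosen by its larger total by a rule fixed before the data were examined, as were the statistics, the gene lists and the other settings to try, except where later choices are named. The fold limits of 1.2 and 1.5 used to describe library differences were set after the data were seen. Gene totals were 4562135 counts in replicate 1 and 5771249 in replicate 2, which were 44.1% of the reads of each file (10353270 and 13084967 reads). Reads in several places made up 30.7% and 31.0%, unmapped reads 20.6% and 20.9%, and reads on no gene of their own strand 4.62% and 4.01%, which take in opposite-strand reads at genes (1.23% and 1.21%). The read classes stayed out of every total. Levels are CPM, counts of a gene per 1000000 counts of the same-strand gene total, and shares are percent of that total. Errors are the SD over the 2 libraries, and 95% Wilson intervals per library were computed for each share. A count of 0 allows up to 3 counts, which is 0.658 CPM in replicate 1 and 0.520 CPM in replicate 2. Reads amplified by PCR without molecular identifiers are not independent molecules, so intervals, floors and the exact binomial test cover counting error only.

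Names, hairpins and positions came from GENCODE release M21 on the same build, GRCm38; 1894 of the 1973 gene identifiers matched by identifier and 79 did not, with 2 and 7 counts in replicates 1 and 2. Each gene was placed in an exon, an intron or between genes of that release. Genes with a count of at least 10 in both libraries were tested. The libraries were scaled by TMM in edgeR 4.0.16 (R 4.3.3), each gene's counts were compared by a two-sided exact binomial test conditional on their sum, and p-values were adjusted by Benjamini-Hochberg at 0.05. The variation between libraries was edgeR's common dispersion with an intercept only, with bounds from 100 bootstrap draws of genes. The binomial test compares the libraries, not conditions.

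The 22 lists of miRNA genes cover families, clusters, imprinted domains and cell types. Each list's median log2 CPM (pseudocount 0.5 reads) was set against 10000 random lists of its size, drawn from the 683 genes with a count or, where a list had members without a count, from all genes of the files. Clusters were tested genes on 1 strand with gaps of at most 10 kb. In the comparison of genes that share a mature sequence, clusters took in all genes with a position, also those not tested. The share of variance between clusters was set against 10000 shuffles of the cluster labels. Genes that share a mature sequence were compared with neighbours in the same cluster by a sign-flip permutation test, with all 524288 sign assignments for its 19 clusters. All these tests were two-sided. The named genes were the 20 with the highest share, up to 3 of the highest members of each list, the 5 genes higher in each library with the largest ratio and a mean count of at least 100, and the highest and lowest member of the 5 most abundant clusters.

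The binomial, dispersion, list, cluster and sign-flip statistics were tested on simulated data, and the percentiles among lists matched on level and the GC correction were not. In 369 simulated genes the binomial test found 57.7% of genes changed 1.2-fold, 82.6% of those changed 1.5-fold, 93.2% of those changed 2-fold and 100% of those changed 4-fold, and called 1.67% of unchanged genes. A simulated coefficient of variation of 20% was estimated as 19.4%. The list test passed 8.33% of 60 random lists at an unadjusted 0.05, and the cluster test passed 6.67% of 60 data sets without similarity.

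Alternatives were the unstranded column, DESeq2 1.42.0 size factors, total counts, TMM-scaled CPM, other count minimums (1 and 100), a pseudocount of 5, cluster gaps of 2 and 50 kb, the total without its most abundant gene, lists of tested genes only, and leaving out each library. Statistics used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6. Target genes were not analysed here.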

Results

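The 2 libraries held short RNA from the facial prominences of mouse embryos at day 13.5, the tissue from which the upper and lower face, palate and nose form. Both were biological replicates of a single group, so the data give the level of each miRNA gene in this tissue and its spread between replicates, and no contrast between conditions. Replicate 1 had 4562135 counts on miRNA genes and replicate 2 had 5771249. Of 1973 annotated genes, 360 had at least 10 counts in both libraries, 683 had a count in at least 1 library and 1290 had none. Of the 360 genes, 161 lay in an intron of a host gene, 83 in an exon, 90 between genes and 26 only opposite a host gene. P-values of the binomial test set the difference between these samples against counting error, and those of the list, cluster and sign-flip tests are over genes or clusters, which are not independent replicates.

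Reads with several places in the genome were not counted, so the ranking understates genes whose mature sequence is encoded at several loci. By uniquely placed reads, Mirlet7i and Mir99a were the most abundant miRNA genes, at 65548 ± 11599 and 65543 ± 9361 CPM (SD, n = 2). Their order differed between the libraries, with Mirlet7i at 7.37% of counts (95% Wilson interval 7.35 to 7.40) in replicate 1 and 5.73% (5.72 to 5.75) in replicate 2, and Mir99a at 5.89% and 7.22%. The let-7 family, which restrains growth-promoting genes as tissues mature, also placed Mirlet7g among the leading genes, at 55052 ± 352 CPM. Mir23b followed Mir99a at 56985 ± 11827 CPM. Mir335, from an intron of the imprinted gene Mest, reached 46814 ± 2257 CPM, and Mir322 of the X-linked Mir322-Mir503 cluster reached 43792 ± 4597 CPM. Mir17, a member of the proliferation-linked Mir17 to Mir92 cluster, stood at 36397 ± 32.0 CPM.

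The leading gene sat on the minus strand of chromosome 10 from 122985640 to 122985724 (GRCm38), in an exon of D630033A02Rik, and its hairpin reads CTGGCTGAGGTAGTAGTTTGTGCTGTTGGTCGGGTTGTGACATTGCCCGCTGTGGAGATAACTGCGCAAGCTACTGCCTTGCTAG. Mir99a lay on the plus strand of chromosome 16 from 77598936 to 77599000, in an intron of Mir99ahg, with the hairpin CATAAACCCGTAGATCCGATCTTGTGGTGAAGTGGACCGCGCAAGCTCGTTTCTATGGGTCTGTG. Mir23b lay on the plus strand of chromosome 13 from 63300484 to 63300557, in an intron of 2010111I01Rik. The first 10 genes together held 46.6 ± 0.335% of counts, and the first 20 held 66.6 ± 0.0180%. In each library 12 genes held 50% of the counts.

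**Figure D1:**
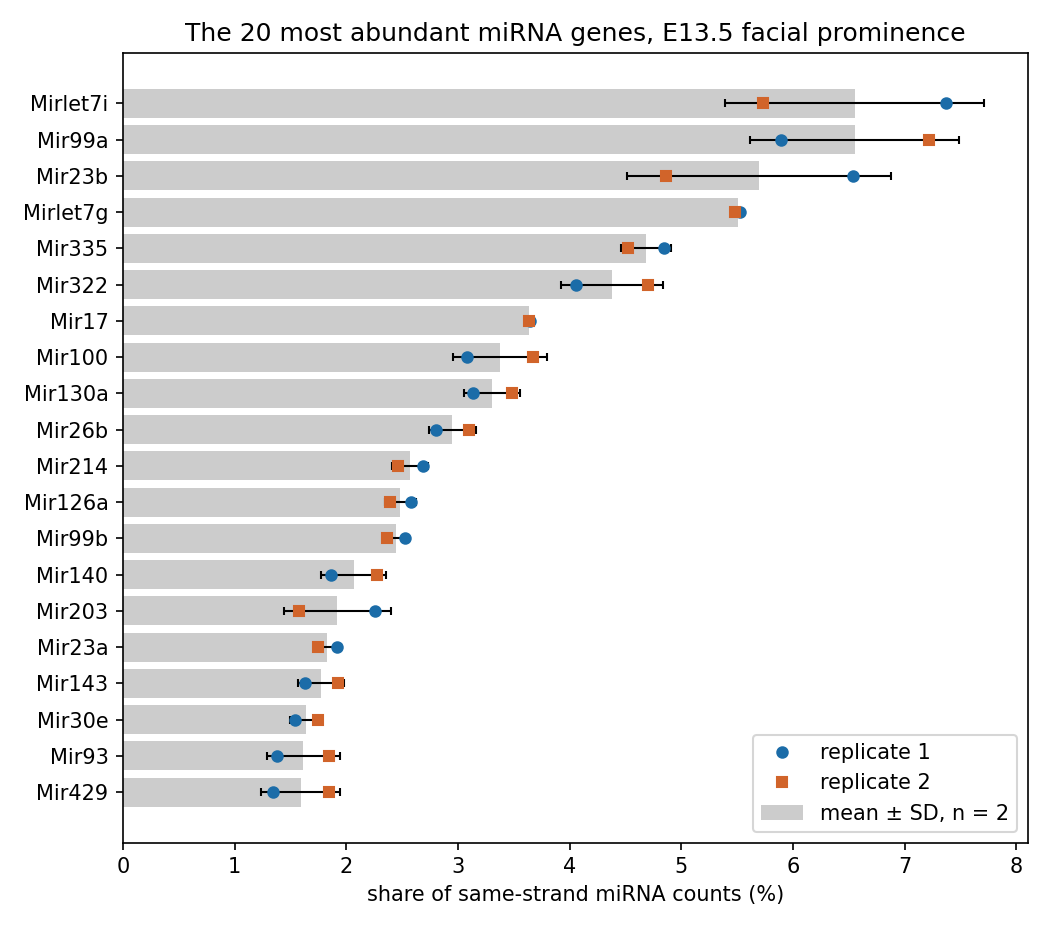
Share of same-strand miRNA counts, in percent, of the 20 miRNA genes with the highest mean share of uniquely placed reads. Bars are means with SD over 2 libraries, circles are replicate 1 and squares replicate 2; Mirlet7i and Mir99a lead with 6.55% each and change places between the libraries.

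Further down the first 20 stood genes tied to the tissues of the face. Mir140, the cartilage miRNA encoded within Wwp2, reached 20657 ± 2904 CPM. Mir214, from the Dnm3os transcript of mesenchyme, reached 25707 ± 1581 CPM, and Mir143, known from smooth muscle and mesenchyme, reached 17775 ± 2059 CPM. Mir203, a regulator of epidermal differentiation, stood at 19190 ± 4787 CPM and Mir429 of the epithelial Mir200 family at 15915 ± 3532 CPM. Mir126a, the endothelial miRNA within Egfl7, reached 24841 ± 1371 CPM. The rest of the first 20 were Mir100 (33766 ± 4173 CPM), Mir130a (33083 ± 2498 CPM), Mir26b (29506 ± 2092 CPM), Mir99b (24434 ± 1106 CPM), Mir23a (18290 ± 1194 CPM), Mir30e (16421 ± 1438 CPM) and Mir93 (16133 ± 3273 CPM).

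Among uniquely placed reads, epithelial, mesenchymal, endothelial and sensory miRNAs stood high, while neural and muscle miRNAs took small shares. The mesenchyme and cartilage list held 6.85 ± 0.349% of counts (SD, n = 2) and the epithelium list 6.34 ± 0.0162%, led in the latter by Mir203, Mir429 and Mir205, a basal epithelial gene at 15023 ± 981 CPM. Mir183, Mir182 and Mir96, known from hair cells and other sensory cells, stood at 9775 ± 635, 9643 ± 759 and 3410 ± 543 CPM. The neural list held 0.0944 ± 0.00405%, led by Mir137 at 310 ± 8.26 CPM, Mir138-2 at 129 ± 16.8 CPM and Mir138-1 at 113 ± 1.51 CPM. The striated muscle list held 0.0519 ± 0.0160%, led by Mir206, a skeletal muscle miRNA, at 442 ± 181 CPM, with Mir208b at 49.8 ± 15.3 CPM and Mir133b at 12.1 ± 1.46 CPM. The main neural and muscle miRNAs, of the Mir124a, Mir9, Mir1a and Mir133a genes, are encoded at several loci. Most other genes of the neural list, among them Mir138-2 and Mir138-1, also share a mature sequence with another locus. In the mesenchyme and cartilage list, Mir199a-1 and Mir199a-2 were named as sharing one. No gene of the epithelium or sensory lists was named as sharing one. Reads with several places in the genome were not counted. The neural, muscle, and mesenchyme and cartilage shares therefore leave such reads out, and the lists were not counted alike.

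Of the 22 lists, 14 lay high by the permutation test and 0 low after Benjamini-Hochberg adjustment. Random lists draw genes as if independent, while levels were more alike within genomic clusters than in shuffles. P-values of lists with clustered members, such as those of sensory epithelium, epithelium, Mir322-Mir503 and Dlk1-Dio3, are therefore too small. The medians of the epithelium list (adjusted permutation p = 0.00147) and of the list tied to facial and palate development (adjusted permutation p = 0.00147) lay above those of nearly every random list. The latter list held 16.8 ± 1.07% of counts, led by Mir23b, Mir17 and Mir140. It shares members with other lists, including Mir200b and Mir203 with the epithelium list, so these results are not independent. Adjusted p was 0.00880 for mesenchyme and cartilage, 0.0172 for sensory epithelium and 0.0497 for endothelium, where Mir126a alone had a place in the files. White blood cell genes did not pass (adjusted p = 0.443), with Mir223 at 373 ± 14.0, Mir155 at 121 ± 25.3 and Mir146 at 61.1 ± 18.7 CPM. Erythroid genes did not pass either (adjusted p = 0.618), with Mir451a at 76.0 ± 14.5, Mir144 at 45.0 ± 28.0 and Mir486 at 9.66 ± 0.914 CPM. The list of liver, gut, pancreas and kidney gave an adjusted p of 0.865, with Mir375 at 877 ± 187, Mir192 at 89.9 ± 7.84 and Mir122 at 79.4 ± 42.3 CPM. The Hox list gave 0.318, with Mir10b at 2326 ± 559, Mir10a at 1070 ± 942 and Mir615 at 100.4 ± 55.5 CPM. The neural (adjusted p = 0.00220), striated muscle (adjusted p = 0.0301) and pluripotent lists (adjusted p = 0.0171, led by Mir302a at 219 ± 0.364, Mir302d at 195 ± 24.3 and Mir302b at 148 ± 17.2 CPM) were set against all genes, most of which had no count. Against tested genes only, these 3 lay below the middle without passing, at the 10.3, 7.03 and 27.1 percentiles. Genes encoded at several loci enter there without their multiply placed reads, among them neural genes and the Mir199a genes of the mesenchyme and cartilage list. In that setting 2 of the 22 lists passed, those of epithelium and of facial and palate development.

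**Figure D2:**
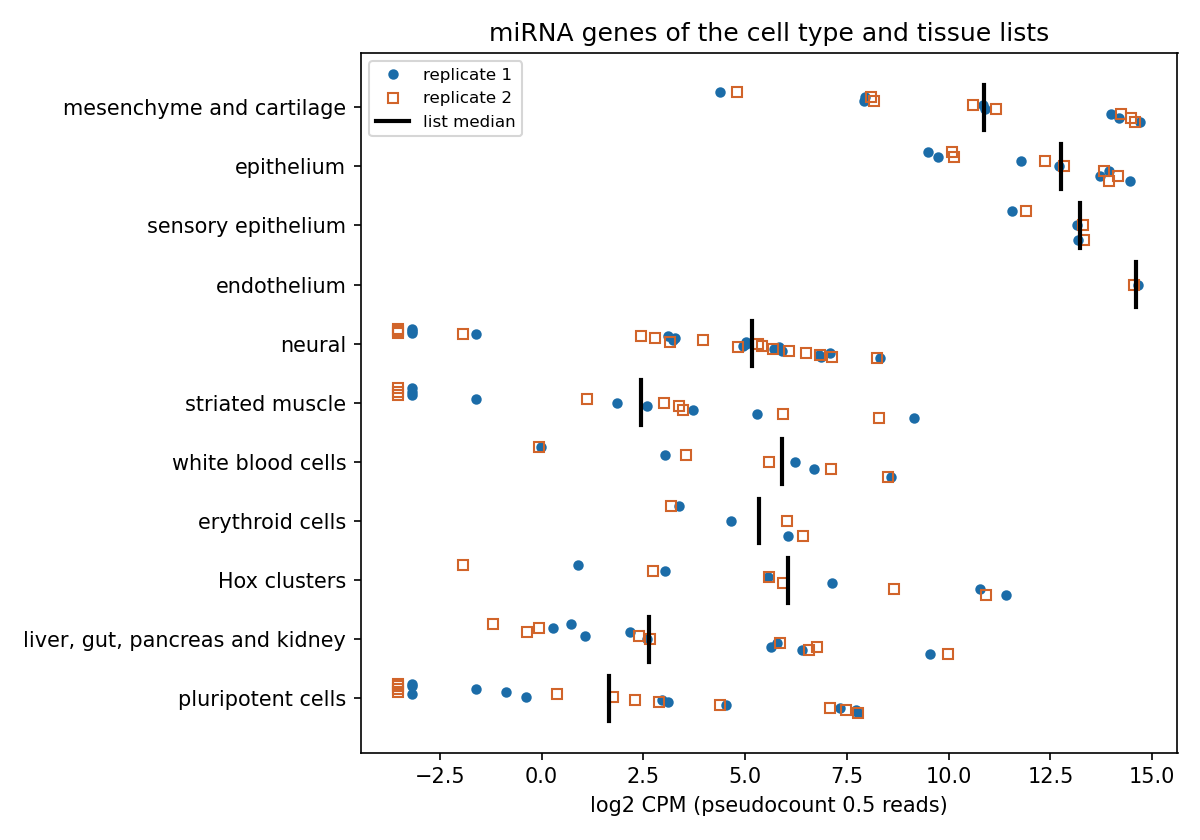
Level of each miRNA gene of 11 cell type and tissue lists, as log2 CPM with a pseudocount of 0.5 reads. Circles are replicate 1, open squares replicate 2 and black bars the list medians; epithelial, sensory, endothelial and mesenchymal medians lie above 10, and muscle and pluripotent medians lie below 2.5.

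The let-7 family held 14.0 ± 1.40% of counts (adjusted permutation p = 0.00352), and Mirlet7d was its next member after Mirlet7g, at 8969 ± 1473 CPM. Mir17 to Mir92 and the related clusters held 8.61 ± 0.512% (adjusted permutation p = 0.0148), led by Mir17, Mir93 and Mir20a, the last at 13445 ± 1314 CPM. The clusters of Mir99 or Mir100 with let-7 and Mir125 held 13.1 ± 1.17% (adjusted permutation p = 0.00367), and those of Mir23, Mir27 and Mir24 held 8.04 ± 1.30% (adjusted permutation p = 0.0296). The X-linked Mir322-Mir503 cluster held 5.00 ± 0.469% (adjusted permutation p = 0.0359), with Mir351 at 4079 ± 16.6 and Mir503 at 984 ± 33.2 CPM. The Mir15 and Mir16 clusters missed the threshold (adjusted permutation p = 0.0519) with Mir15a at 2851 ± 161, Mir16-1 at 1601 ± 241 and Mir15b at 1030 ± 51.7 CPM. The families of Mir29, Mir30 and Mir26 (adjusted permutation p = 0.214) held 5.55 ± 0.396%, mostly Mir26b and Mir30e, with Mir30a at 5153 ± 293 CPM. Of these, the calls for let-7, Mir17, Mir99, Mir23 and Mir322 were lost among tested genes only. Each of these families and clusters has members that share a mature sequence with another locus. Their multiply placed reads were not counted, so the shares, the order of members and the list tests leave such reads out.

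The Dlk1-Dio3 imprinted domain, whose miRNAs are transcribed from the maternal chromosome, was broadly active. Of the 40 tested genes of its list, which does not take in every miRNA gene of the domain and lies between 109563692 and 109743795 on chromosome 12 (GRCm38), 12 exceeded 1000 CPM. The list held 4.55 ± 0.236% of counts (SD, n = 2). Its adjusted permutation p was 0.00147 against all annotated genes, most of which had no count, and 0.165 among tested genes only. Mir411 led at 7135 ± 1.27 CPM, followed by Mir487b at 6027 ± 709 CPM and by Mir127, which lies opposite Rtl1, at 5585 ± 435 CPM. Mir335 in Mest stood above the other imprinted-host miRNAs, Mir483 in Igf2 at 991 ± 141 CPM and Mir675 in H19 at 89.7 ± 0.0737 CPM; the 3 together gave an adjusted permutation p of 0.139. The list for the repeat cluster in an intron of Sfmbt2 was drawn up by gene name, without a check of position. Of its 69 genes, 10 had counts of at least 10 in both libraries and 46 had no count. Mir467d stood at 2299 ± 301, Mir467e at 2086 ± 12.5 and Mir467c at 1975 ± 96.6 CPM. The adjusted permutation p was 1.0 against all annotated genes. The medians of the list and of all annotated genes were both at a count of 0, so that test could not place the list. Multiply placed reads were not counted, so genes of this list that share sequence may be undercounted.

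**Figure D3:**
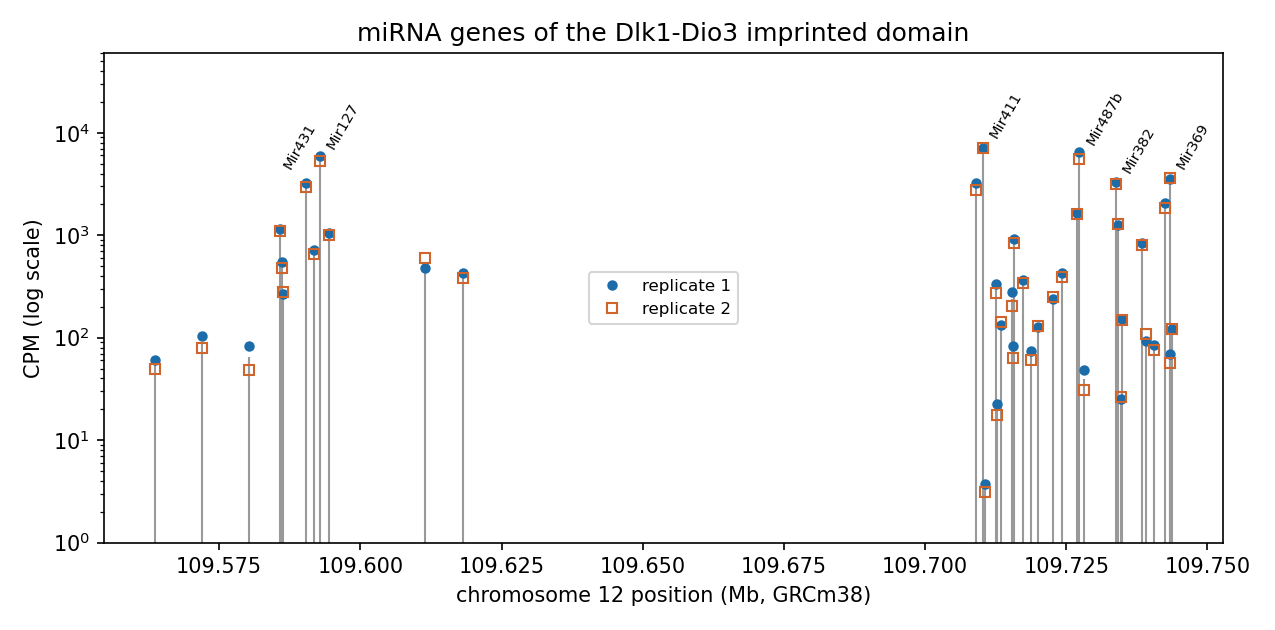
CPM, on a log scale, of the 40 tested miRNA genes of the Dlk1-Dio3 list, which leaves out some genes of the domain, against their position on chromosome 12 in megabases. Circles are replicate 1 and open squares replicate 2, and grey lines reach the mean; Mir411 is highest, and 29 of the genes lie within 1.2-fold between the libraries.

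Neighbouring miRNA genes, which are often cut from 1 transcript, had more similar levels than shuffled genes, yet members of a cluster still spanned wide ranges. Over 43 clusters with 150 tested genes, 41.1% of the variance of log2 CPM lay between clusters, against 28.2% in shuffles (permutation p = 0.0140). In the Mir17 cluster, Mir17 exceeded Mir19b-1 (15.9 ± 3.86 CPM) by 2289-fold. Mir322 exceeded Mir450-2 (13.4 ± 0.380 CPM) by 3263-fold, Mir99a exceeded Mirlet7c-1 (136 ± 5.80 CPM) by 482-fold, Mir100 exceeded Mirlet7a-2 (226 ± 30.1 CPM) by 149-fold and Mir23b exceeded Mir27b (4543 ± 47.7 CPM) by 12.5-fold. Mir19b-1, Mir450-2, Mirlet7c-1 and Mirlet7a-2 share a mature sequence with another gene, and such genes lay below their neighbours in 18 of 19 clusters, with a median log2 difference of -4.79 (sign-flip permutation p = 0.0117). Levels of these genes are therefore uncertain, including those of Mir1a-1, Mir133a-1, Mir133a-2, Mir124a-1, Mir124a-3 and Mir9-2, which had 0 uniquely placed counts. A count of 0 sets no upper limit on their level, because multiply placed reads were not counted.

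Between the libraries, Mir10a differed most among genes with a mean count of at least 100, at 1737 CPM in replicate 1 and 404 CPM in replicate 2, a 4.30-fold difference. Mir10a lies in the Hoxb cluster, and Mir615, in an intron of Hoxc5, was also higher in replicate 1, by 2.28-fold (adjusted p = 2.06e-36, exact binomial test). The others of the 5 genes highest relative to replicate 2 were Mir6236 and Gm23935, at log2 ratios of replicate 2 to replicate 1 of -1.16 and -0.96, and Mir128-2, at 56.6 CPM in replicate 1 and 28.2 CPM in replicate 2. Higher in replicate 2 were Mir144 of red blood cells, by 2.56-fold, and Mir122 of liver, by 2.20-fold, followed by Mir7b, Mir383 and Mir204, at log2 ratios of 0.93, 0.92 and 0.86.

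Cell type lists moved in part between the libraries. Of 7 epithelial genes, 5 were higher in replicate 2, among them Mir200b (log2 ratio 0.59), Mir200a (0.58) and Mir429 (0.46), while Mir203 (-0.51) and Mir205 (-0.13) were higher in replicate 1; all 7 passed adjusted over the list alone. Of 8 mesenchyme and cartilage genes, 6 were higher in replicate 2, including Mir140 (0.29) and Mir143 (0.24), and 2 higher in replicate 1, including Mir214 (-0.13); all 8 passed adjusted over the list alone. Among 5 tested muscle genes, Mir206 was higher in replicate 1 (-0.86) and 3 were higher in replicate 2, including Mir208b (0.63), of heart and slow muscle; 4 passed adjusted over the list alone. In the Dlk1-Dio3 list 21 genes were higher in replicate 1, 3 in replicate 2 and 16 did not pass; 24 passed adjusted over the list alone. Of 5 tested Hox-cluster genes, Mir10a, Mir615 and Mir10b (-0.50) were higher in replicate 1 and Mir196a-2 (-0.30) and Mir196b (0.02) did not pass; 3 passed adjusted over the list alone.

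Across all 360 tested genes, 198 differed by more than counting noise in the exact binomial test after Benjamini-Hochberg adjustment, 98 higher in replicate 1 and 100 higher in replicate 2. Of all 360 tested genes, whether past the test or not, 197 (54.7%) lay within 1.2-fold between the libraries. Of the 198 genes past the test, 40 differed by over 1.5-fold. Over the 360 genes the chi-square was 79770 on 359 degrees of freedom, set against counting error only. The coefficient of variation between libraries beyond counting noise was 18.0% (bootstrap bounds 15.0 to 20.3%). Across genes, which are not independent replicates, Pearson's r of log2 CPM was 0.993 and Spearman's rho 0.991. Log2 ratios were also more alike within clusters than in shuffles (54.2% against 28.2% of variance, permutation p = 0.0002, the smallest that 10000 shuffles can give).

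**Figure D4:**
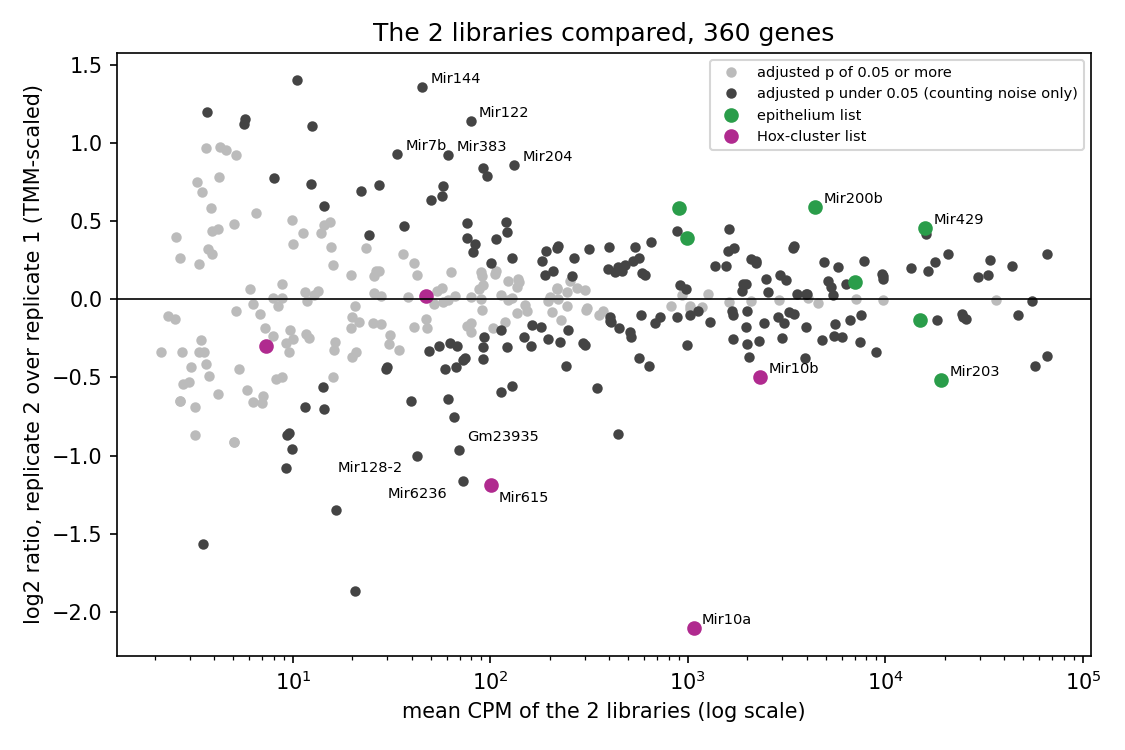
Log2 ratio of replicate 2 to replicate 1 after TMM scaling, against mean CPM on a log scale, for 360 tested genes. Dark points passed the exact binomial test at an adjusted 0.05 and light points did not; Mir10a lies lowest at -2.10, and epithelial genes (green) and Hox-cluster genes (magenta) are marked.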

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

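The tests on opposite-strand counts were chosen only after the result was seen. Counts outside the analysed column came to 126885 on the opposite strand in replicate 1 and 158904 in replicate 2. Reads placed at several loci, 3179149 in replicate 1 and 4058237 in replicate 2, have no gene in the files and were not assigned. All of these lie above the 3 counts that a count of 0 allows.

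Opposite-strand counts piled up at 11 genes. All 11 lie opposite a known miRNA gene: Gm25301, opposite Mir378a, had a mean of 8141 CPM there, Gm25927, opposite Mirlet7e, 5649 CPM, Gm24321, opposite Mir409, 5165 CPM, and Gm24083, opposite Mir191, 2987 CPM. Gm25252, opposite Mir376a, had 1857 CPM, Mir299b, opposite Mir299a, 1340 CPM, Mir497b, opposite Mir497, 1049 CPM, and Gm25750, opposite Mir380, 830.3 CPM. Mir142b, opposite Mir142, had 389.5 CPM, Mir3074-1, opposite Mir24-1, 118 CPM, and Gm24111, opposite Mirlet7f-1, 100.3 CPM.

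Imperfect strand marking is argued against, because over genes with no miRNA gene on the other strand the opposite-strand counts were at most 0.00420% of the same-strand counts in either library. In each library 99.9% of opposite-strand counts, after rounding, lay at genes overlapped by a miRNA gene that has no place of its own in the files. A candidate explanation is that these are reads of Mir378a, Mirlet7e, Mir409, Mir191 and the others, counted at the overlapping gene. On that reading the same-strand total lacks these genes, as do the lists that name them, those of let-7, Dlk1-Dio3, white blood cells, facial and palate development, Mir23 with Mir27 and Mir24, Mir99 with let-7 and Mir125, and Mir15 with Mir16, whose adjusted permutation p of 0.0519 was computed without Mir497. The design gives no biological alternative, and none was tested.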

How the results depend on the processing

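The 2 further definitions in the paralog comparison (hairpins sharing 20 bases, and tested genes only) were chosen after seeing the data; all other alternatives were planned. The share of the first 10 genes was 45.4% with the unstranded column, against 46.6%, a change that follows from the larger total. With the most abundant gene left out of both the sum and the total, the rest of the first 10 held 42.9%. That fall follows from leaving the gene out of the sum. With a minimum of 1 count, 552 genes were detected, against 360. Among tested genes only, 2 of 22 lists passed, against 14; the pool then holds far fewer low genes. Percentiles there were 99.1 for let-7, 87.6 for Mir17 to Mir92 and related clusters, 98.2 for mesenchyme and cartilage, 98.6 for sensory epithelium, 96.9 for endothelium, 97.4 for Dlk1-Dio3, 91.0 for Mir322-Mir503, 94.0 for Mir23, Mir27 and Mir24, and 99.3 for Mir99, let-7 and Mir125, none past the threshold. Neural (10.3), striated muscle (7.03) and pluripotent lists (27.1) fell below the middle. The log2 ratios of Mirlet7g and Mir17 turned from -0.01 and -0.0023 to 0.011 and 0.022 without the filter on low counts, where the scaling shifts all genes alike. Of named gene levels, 25 of 71 moved by over 1 SD with the most abundant gene left out of the total and 11 of 72 with the unstranded column; leaving out either library cannot move a mean of 2 by that much. The paralog difference kept its direction and its side of the threshold under all 7 alternatives, as did the cluster similarity of levels under 5. Genes beyond counting noise numbered 197 to 209 over 4 alternatives, and coefficients of variation stayed within the bootstrap bounds. Without the filter on low counts, 683 genes were tested and 183 of the 198 main calls were kept. DESeq2 size factors kept 197, and total counts and the unstranded column kept 198. Low counts limit genes near 10 counts. No paired analysis was possible because there is only 1 group.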

Other observations

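The percentiles among lists matched on level, the GC correction and the test without Mir10a, and the definitions of shared sequence by 20 bases and by tested genes only, were chosen only after the result was seen; the binomial test and the paralog comparison itself were planned.

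Several abundant families stood outside the lists. Mir130a and Mir130b together held 4.06 ± 0.212% of counts (SD, n = 2), and the 6 genes of the Mir181 family held 1.85 ± 0.186%, led by Mir181c at 7774 CPM. Mir181a-1, Mir181a-2, Mir181b-1 and Mir181b-2 share a mature sequence with another locus. The Mir181 share and the lead of Mir181c therefore leave out their multiply placed reads. Mir652 held 0.975 ± 0.00336%, Mir149 0.744 ± 0.0994%, Mir744 0.660 ± 0.0433% and Mir151 0.634 ± 0.0303%. Mir21a, a widely expressed miRNA known for its rise in injured and tumour tissue, held 0.575 ± 0.0583%. Mir423 held 0.529 ± 0.0202%, Mir296 0.478 ± 0.0601% and Mir342 0.398 ± 0.0344%. These families were chosen after their values were seen.

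Genes that share a mature sequence had fewer counts than their cluster neighbours, by a median log2 difference of -4.79 over 19 clusters, with Mir26a-2, above the rarely counted Mir546, the single exception. The bound for reads shared between paralogs being left out of the counts was a difference below -2, set before the result was seen. Such genes lose reads by construction, because multiply placed reads were not counted, so passing the bound is no independent support. With genes sharing 20 bases of hairpin the difference was -2.55, lower in 24 of 30 clusters. Among tested genes only it was -4.99, lower in 14 of 14, and -4.96, lower in 14 of 16, by the 20 bases. These values are consistent with loss of multiply placed reads, while differences in processing between hairpins of 1 transcript were not tested and could also contribute.

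Of 5 tested Hox-cluster miRNAs, 3 were higher in replicate 1 and 2 did not pass the test, and the median log2 ratio was -0.50, at the 0.667 percentile of 100000 lists matched on level. GC content as the whole cause is argued against, since after a GC correction the median was -0.45, still at the 0.600 percentile. More tissue of Hox-expressing segments in replicate 1, such as neck or trunk at the edge of a dissection, may contribute. However, the other 4 genes without Mir10a lay at the 5.031 percentile, against a bound of 5. These 4 still held Mir615 (log2 ratio -1.19), which was also named for its difference between the libraries, so this percentile is no independent support. In 20 sets of 10000 matched lists this percentile ran from 4.27 to 5.66 and fell below 5 in 10 sets, and after the GC correction it was 4.16, so the side depends on the draw of lists and on the correction, and that explanation stays open. The design names no difference between the libraries.

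Other lists also lay toward an end of 10000 lists matched on level in their median log2 ratio of replicate 2 to replicate 1. The percentile was 99.99 for epithelium (median 0.39), 99.3 for striated muscle (0.63), 99.1 for mesenchyme and cartilage (0.25), 0.335 for Dlk1-Dio3 (-0.14) and 1.97 for let-7 (-0.16). The summed shares of the epithelium list were 6.35% in replicate 1 and 6.33% in replicate 2, since Mir203 and Mir205 were lower in replicate 2. The summed shares of the striated muscle list went the other way from its median, at 0.0632% in replicate 1 and 0.0406% in replicate 2, since Mir206 holds most of its counts. The matched lists draw genes as if independent, while ratios were alike within clusters, so percentiles of lists with clustered members are too extreme.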
